A study of Arabidopsis thaliana with 12 samples.

How the data were processed

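Arabidopsis thaliana rosette leaves of the Columbia accession were profiled by chromatin immunoprecipitation sequencing (ChIP-seq) and by RNA sequencing. Per the labels, the plants were 4 weeks old and grew under 16 h of light at 22 °C and 8 h of dark at 20 °C. The time of day of harvest is not given in the sources used here. The genotypes were wild type, an atx3/4/5 mutant and an sdg2 mutant. The ChIP-seq part holds 1 sample per genotype and antibody: H3K4me2 and H3K4me3 in wild type and atx3/4/5, H3K4me3 in sdg2, and 1 input per genotype. The RNA-seq part holds 2 samples each of wild type and atx3/4/5. Samples were placed in groups by their titles and genotype labels.

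The H3K4 peak lists were used as deposited. Per the submitters' processing notes, the tools were Bowtie 1.0.1 and MACS 1.4.2 for the ChIP-seq reads, with the TAIR10 build. The role of each tool is inferred from its usual use, since the notes give names and versions only. Each list comes from 1 ChIP sample, and its label names an input as the control, so peaks were called per sample and not on pooled samples. The fifth column is a score given by the authors' peak caller, read here as 10 times the negative log10 of the peak p-value. The lowest score over the deposited lists was 50, which corresponds to a p of 1e-05 under that reading. Scores were used only to rank, filter or bin peaks within a list, except where scores of 2 lists are said to be matched or weighted, or median scores are set side by side. All 5 lists cover nuclear chromosomes only. Read depth of the ChIP-seq libraries is unknown, and the inputs themselves were not analysed here.

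For the RNA-seq part the authors' deposited table gives 1 FPKM value per gene and genotype (fragments scaled by transcript length and by library size), a status, a p-value and a q-value. Per the submitters' processing notes, TopHat2 2.0.10 and Cufflinks 2.2.1 were used with TAIR10, and the column layout is that of a Cuffdiff gene comparison. The 2 libraries of a genotype are combined into 1 value by the authors, so no spread between libraries can be given and no test of replicates was run here. The p-values and q-values are those of the authors' deposited table. Nothing in the labels says whether the 2 libraries of a genotype came from separate plants, so these p-values may measure a technical spread. The q-values equal a Benjamini-Hochberg adjustment over the tested genes. RNA read depth is unknown. Antisense and overlapping genes cannot be told apart here, since the use of strand is not given in the sources used here. Overlapping genes share 1 locus in the table, which concerned 4249 of 33557 genes, and near-identical copies such as members of the LHCB1, LHCB2, RBCS and SAUR families may share reads, so their values are uncertain.

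The log2 column of the table was not used, because a spreadsheet had replaced some of its cells with an error mark. No column of per-sample values was left unused (0 columns). Of the genes 14535 were not tested by the authors and 1 had a status for too many reads. Fold changes were computed as the log2 ratio of the deposited FPKM values, atx3/4/5 over wild type, with no pseudocount. A gene was called when its status was OK and its deposited q was under 0.05. Gene names come from a RefSeq gene table of assembly TAIR10.1, used for names only, which matched 32810 of the 33557 gene identifiers. Gene positions are those of the authors' deposited table, on TAIR10, counted from 1. A gene list was compared with 10000 random lists of the same size drawn from the tested genes and matched on mean FPKM in 20 bins. The percentile of its median among them is a description of these libraries and not a test of replicates. A list outside the central 95% of the random lists is said to stand apart. The length of a gene is the length of its locus.

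A peak of wild type was absent in a mutant when no mutant peak overlapped it by at least 1 bp, and a mutant peak with no overlapping wild-type peak was called gained. A gene carried a mark when a peak overlapped its locus by at least 1 bp. With 1 ChIP library per genotype and mark there is no replicate check and no p-value. Shares are given with exact (Clopper-Pearson) 95% confidence intervals, which cover counting error only. Genes that lost H3K4me3 in both mutants were set beside the number from independent lists and beside 1000 draws of independent losses matched on the wild-type peak score in 20 bins. The position of peaks relative to the start of transcription, planned at first, was left out, since no strand or gene model of the build was used here.

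The procedures were tested on simulated data. For the gene lists, over 19021 genes, 7% of 100 simulated lists of 12 genes with no shift stood apart, as did 67% with a shift of 1.0 and 100% with a shift of 2.0 on the log2 scale. For 24 genes, 91% of lists with a shift of 1.0 stood apart. Each simulated value was drawn independently from 1 normal distribution, with no trend along FPKM or gene length and no co-expression. These shares therefore need not hold for lists of co-regulated genes. For shared losses, over 14496 peaks and 20 simulations, the ratio of observed to drawn losses averaged 1.01 with no shared effect and 2.32 with 5% of peaks lost in both.

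The groups, the comparisons, their thresholds, the 21 gene lists (368 genes) and the rule for named genes were chosen before the data were examined. The lists are H3K4 methyltransferases and COMPASS subunits, H3K4 demethylases, flowering time, circadian clock, salicylic acid and pathogen defence, jasmonate and wounding, photosynthesis, abscisic acid with drought and cold, heat shock and chaperones, auxin response, expansins with xyloglucan endotransglucosylases (XTH), cell proliferation, leaf senescence, floral and meristem regulators, flavonoids, glucosinolates, iron, stomatal lineage, vascular, root hair and reference genes. By that rule the text names the targeted genes, the 10 called genes with the largest rise and the 10 with the largest fall at an FPKM of at least 1 in both genotypes, and per list up to 4 called members or, where none was called, the 2 with the highest wild-type FPKM. Of the peaks it takes the 5 highest-scoring absent and gained ones per comparison. Of the genes that lost a mark it takes the 10 with the largest fall and the 5 with the largest rise. List members that lost or gained a mark may be named too. Of the comparisons of a list with a mark with a percentile outside 2.5 to 97.5, 1 is not reported here. The alternatives tried were a q of 0.01, an absolute log2 fold change of at least 1, an FPKM filter, pseudocounts of 1 and 0.1, centring, an overlap of at least 50% of the peak, a gap of up to 200 bp, a score of at least 100, equal numbers of peaks, and gene loci extended by 500 bp. Alternatives that account for gene length or use only genes with a locus of their own were chosen after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.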

Results

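The series was set up to find the genes and genomic regions under the control of ATX3, ATX4 and ATX5, a group of putative histone H3 lysine 4 (H3K4) methyltransferases of Arabidopsis. H3K4me3 marks mainly the beginnings of transcribed genes, and H3K4me2 covers gene bodies and poorly transcribed genes as well. SDG2 (also ATXR3) is a further H3K4 methyltransferase of the plant, and its mutant was profiled for H3K4me3. The data comprised 5 peak lists, from 1 ChIP-seq library each, and 1 RNA-seq comparison of atx3/4/5 with wild type made by the authors from 2 libraries per genotype. No spread between libraries can be given for any value below.

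In the RNA comparison, most salicylic acid and pathogen defence genes were called higher in the mutant. The called genes of the cold, jasmonate, auxin and photosynthesis lists were mostly lower. Of 19021 genes tested in the authors' deposited table, 1964 were called, 936 higher and 1028 lower in atx3/4/5. At an unadjusted p under 0.05 the number was 4869 in the authors' deposited table. Of the calls, 44 were listed at 0 in wild type and 29 at 0 in atx3/4/5 in the authors' deposited table. The smallest absolute log2 fold change among the calls of the authors' deposited table was 1.26. The median log2 fold change of the 16448 genes with an FPKM of at least 1 in both genotypes was -0.06 in the authors' deposited table. No call rests on a test of single libraries made here.

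The targeted genes did not separate the genotypes. ATX3 (AT3G61740) had an FPKM of 4.38 in atx3/4/5 and 4.17 in wild type, and ATX5 (AT5G53430) had 3.76 and 3.93, with q-values of 0.941 and 0.945 in the authors' deposited table. ATX4 (AT4G27910) stood at 2.88 in the library pair labelled atx3/4/5 and 1.05 in wild type, 2.75-fold apart but not called, with a q of 0.0541 in the authors' deposited table. An FPKM over the whole gene need not fall when an insertion disrupts a gene, so these values check the genotype labels in neither direction. The libraries are therefore named as labelled throughout. SDG2 (AT4G15180; chromosome 4, 8651406 to 8662587) was 4.02-fold higher in atx3/4/5, from 0.884 to 3.55, with a q of 0.00184 in the authors' deposited table. SDG8 (AT1G77300), a methyltransferase known mainly for H3K36, was 3.44-fold higher, with a q of 0.0127 in the authors' deposited table. They were the only calls among the 12 H3K4 methyltransferases and COMPASS subunits, 4 of which were higher when adjusted over the list alone. The list median was 0.91 in log2 at the 96.9 percentile of random lists, within their central range. Its members are long, with a median locus of 6276 bp, and long genes as a class had higher values in the mutant, as described below. After centring within deciles of gene length the list median was 0.38.

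Among called genes with an FPKM of at least 1 in both genotypes, the largest rise belonged to PR1 (AT2G14610; chromosome 2, 6241704 to 6242463), the classical marker of salicylic acid signalling, which went from an FPKM of 19.4 in wild type to 1634 in atx3/4/5 in the authors' deposited table, 84.3-fold. It was followed by AT2G43570, an annotated chitinase (CHI), at 60.1-fold, and by the nitrilase NIT2 (AT3G44300) at 49.4-fold in the authors' deposited table. AT5G09570 (44.8-fold), EARLI1 (36.1-fold), PR2 (35.5-fold), AT4G10500 (34.8-fold), AT5G51440 (33.1-fold), MSRB8 (32.9-fold) and AT1G21525 (26.7-fold) completed the 10 largest rises above that floor in the authors' deposited table. PR2 is a secreted glucanase of the defence response, and MSRB8 repairs oxidised methionine. At the other end and above the same floor, AT3G01345 (chromosome 3, 129138 to 130749) was 91.1-fold lower in the authors' deposited table, from 221 in wild type to 2.42. SADHU5-1 (AT4G01525), a non-coding retrotransposon, was 26.3-fold lower, and AT1G58280, AT4G27360 and AT1G55675 were 25.6-fold, 25.6-fold and 23.4-fold lower in the authors' deposited table. Then came AT3G15780 (22.9-fold), the non-coding AT2G41312 (log2 fold change -4.19), AT4G01390 (18.1-fold), AT1G23950 (17.8-fold) and AT1G70985 (17.8-fold), all lower in the authors' deposited table. Each of these 20 genes had the smallest q that occurs there, 0.00184.

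Most defence genes of the salicylic acid pathway were higher. Of 24 members measured, 16 were higher and none lower in the authors' deposited table, and 20 were higher when adjusted over the list alone. PR1, the immune monooxygenase FMO1 (log2 fold change 5.34), PR2 (5.15) and the camalexin enzyme PAD3 (4.98) had the largest values in the authors' deposited table. FMO1 and PAD3 had wild-type FPKM values of only 0.185 and 0.695 there, so their folds rest on a low base. The salicylic acid synthesis gene ICS1 (3.40-fold) and the regulators EDS1 (4.61-fold) and PAD4 (2.98-fold) were higher as well in the authors' deposited table. The list median was 2.36, above every one of the 10000 random lists, and it was 2.36 also after centring within deciles of gene length. Among 11 senescence genes measured, SAG13 (4.32) and WRKY6 (1.76) were higher in the authors' deposited table, 4 were higher when adjusted over the list alone, and the list median of 0.13 lay at the 90.2 percentile. Without members under an FPKM of 1 in both genotypes the median was 0.33 and stood apart, at the 98.1 percentile. BIP3, an endoplasmic reticulum chaperone of the unfolded protein response, was 32.9-fold higher in the authors' deposited table, from an FPKM of only 0.48 in wild type. It was the only call among 10 heat shock and chaperone genes, of which 2 were higher and 1 lower when adjusted over the list alone (median 0.38, 85.7 percentile, and 0.09 after centring within length deciles).

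Jasmonate genes moved in both directions. The vegetative storage protein genes VSP1 (log2 fold change 4.63) and VSP2 (3.00) and the thionin gene THI2.1 (2.26) were higher in the authors' deposited table. In contrast, the repressor gene JAZ7 (-2.99), the biosynthesis genes AOS (-2.17), AOC1 (-2.02) and OPR3 (-1.76), and JAZ9 and MYC2 were lower in the authors' deposited table. That makes 3 of 23 members higher and 6 lower in the authors' deposited table, and 4 higher and 9 lower when adjusted over the list alone. The list median was -1.03, at the 0.01 percentile of random lists, and -0.73 after centring within length deciles.

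Cold and abscisic acid genes fell where they were called. CBF2, a transcription factor of cold acclimation, was 13.8-fold lower in the authors' deposited table, at an FPKM of 0.631 in atx3/4/5. Among its known downstream genes, ERD10, COR15A and COR47 fell too, by 3.12, 2.91 and 1.68 on the log2 scale in the authors' deposited table. Other cold genes of the list were not called there: COR15B (-1.33), KIN2 (-0.58), RD29A (-0.38) and KIN1 (0.20). NCED3, which makes the first committed step of abscisic acid synthesis, fell by 2.38 in log2, and the galactinol synthase gene GOLS2 fell by 1.78 in the authors' deposited table. Of 25 members measured, 6 were lower and none higher in the authors' deposited table, and 7 were lower when adjusted over the list alone. The list median of -1.03 lay below all random lists, and it was -0.73 after centring within length deciles. Among photosynthesis genes, PSAL fell 4.11-fold, LHCA4 3.63-fold, PSAK 3.54-fold and LHCB1.1 3.45-fold in the authors' deposited table. They encode subunits of photosystem I and of the light-harvesting antennae. LHCA4 shares its locus with another gene, and LHCB1.1 has near-identical neighbours, so both values are uncertain. The other 27 of 31 members were not called in the authors' deposited table, and 12 of the 31 were lower when adjusted over the list alone. The list median was -1.32, below all random lists, and -1.04 after centring within length deciles.

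Called genes of the auxin response list and of the expansin and XTH list were mostly lower. Of 21 auxin response genes, IAA29 (-2.21), IAA3 (-1.72) and SAUR21 (-1.60) were lower and GH3.3 (1.53) was higher in the authors' deposited table. When adjusted over the list alone 6 were lower and 1 higher, and the median of -1.07 lay below all random lists. Their median locus was 1149 bp, and short genes as a class were lower in the mutant. After centring within length deciles the median was -0.58. Of 20 expansin and XTH genes, which loosen or remodel the cell wall, XTH17 (-2.65), EXPA5 (-2.32) and EXPA3 (-1.72) were lower and XTH23 (2.59) was higher in the authors' deposited table. Adjusted over the list alone, 7 were lower and 2 higher, and the median of -0.56 did not stand apart (12.3 percentile) and was -0.25 after centring within length deciles.

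In the remaining lists 1 gene or none was called. GI, a clock gene, was 3.66-fold higher and the only call among 17 clock genes in the authors' deposited table (median 0.34, 93.7 percentile, and 0.17 after centring within length deciles). GSTF12, needed for anthocyanin transport, was lower at -2.00 among 18 flavonoid genes, and MYB34, a regulator of indole glucosinolates, was lower at -2.00 among 20 glucosinolate genes in the authors' deposited table. Their list medians were -0.67 (2.79 percentile) and -0.07 (84.9 percentile). Against random lists matched on FPKM and gene length the 15 flavonoid genes with a locus of their own stood apart, with a median of -0.70 at the 1.88 percentile. SUC2, the sucrose transporter of phloem companion cells, was lower at -1.66 among 7 vascular markers in the authors' deposited table, with a list median of -0.24 at the 31.7 percentile. In each of these 4 lists the same number of genes was called when adjusted over the list alone. Among 15 flowering time genes tested no member was called in the authors' deposited table, where 1 was higher and 1 lower at an unadjusted p under 0.05 (median 0.14, 70.6 percentile). TEM2 stood at 160 in atx3/4/5 and 213 in wild type, and TEM1 at 144 and 70.0, in the authors' deposited table. None of the 6 H3K4 demethylase genes tested was called in the authors' deposited table, where 4 were higher at an unadjusted p under 0.05. JMJ14 had a log2 fold change of 1.29 and FLD of 0.98 in the authors' deposited table, and the list median of 0.998 lay at the 95.9 percentile. After centring within length deciles the median log2 fold change was 0.60. These genes are long as well, with a median locus of 5362 bp.

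No cell proliferation gene was called among 30 in the authors' deposited table, with 4 higher and 2 lower at an unadjusted p under 0.05 (median 0.35, 81.7 percentile; CYCD3;2 -0.96 and PCNA2 -0.29). The 9 floral, embryo and meristem regulators tested gave no call and no unadjusted p under 0.05 in the authors' deposited table (median 1.09, 93.4 percentile; STM 0.81 and KNAT6 0.55). Iron genes (8 tested, median -0.57, 15.4 percentile) gave no call and 1 lower gene at an unadjusted p under 0.05 in the authors' deposited table, with FPKM values of 235 in both genotypes for the ferritin gene FER1 and of 97.8 against 156 for OPT3. Among 6 stomatal lineage markers no member was called or had an unadjusted p under 0.05 in the authors' deposited table (median -0.37, 17.1 percentile; SCRM -0.22 and TMM -0.53). In none of the lists without a call was a member called when adjusted over the list alone. None of the 6 root hair markers was tested in the authors' deposited table. The 9 reference genes gave no call and 1 lower gene at an unadjusted p under 0.05 in the authors' deposited table. Their median of 0.25 stood apart at the 98.0 percentile, since random lists of similar FPKM had a median of -0.47. The list median turned to -0.09 after centring within length deciles. Against random lists matched on FPKM and gene length, the 8 of them with a locus of their own had a median of 0.31 and still stood apart, at the 97.6 percentile. EF1A and GAPC1, at 0.98 and 0.81, were the most abundant of them in the wild type of the authors' deposited table.

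**Figure D1:**
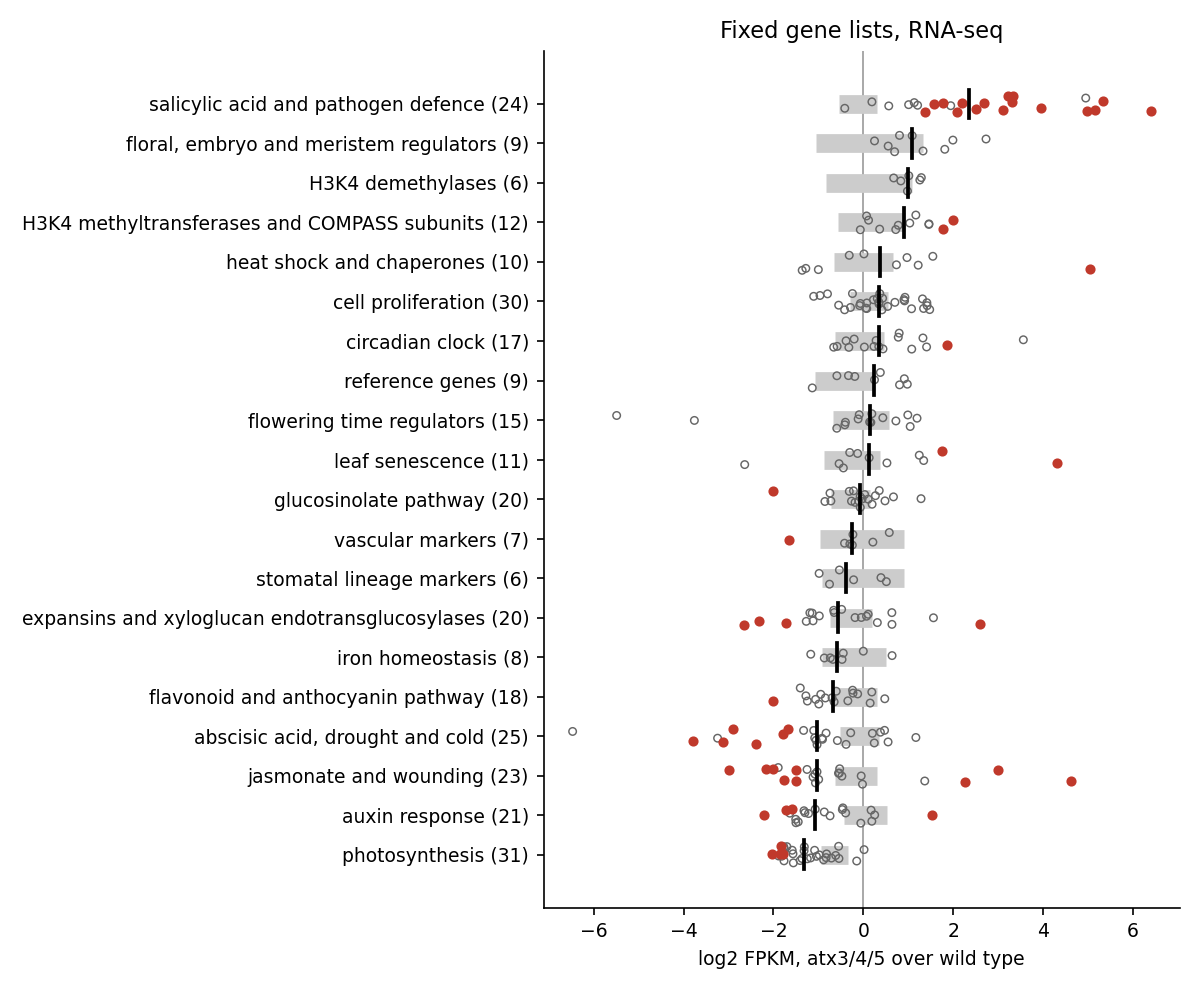
Log2 ratio of FPKM in atx3/4/5 over wild type (x axis) for the tested members of 20 gene lists (y axis, number of members in brackets), from the authors' deposited table. Filled red points are called genes, open points are other members, black bars are list medians and grey bands hold the central 95% of medians of random lists; the defence list has its median at 2.36 and the photosynthesis list at -1.32.

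Fold changes followed gene length. Over genes with a locus of their own and an FPKM of at least 1 in both genotypes, the median log2 fold change in the authors' deposited table climbed in every step from -0.66 in the shortest decile, up to 939 bp, to 0.68 in the longest, from 4329 bp. Of the shortest 1359 genes 49 were called higher and 215 lower in the authors' deposited table, and of the longest 1358 genes 154 were higher and 17 lower.

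**Figure D2:**
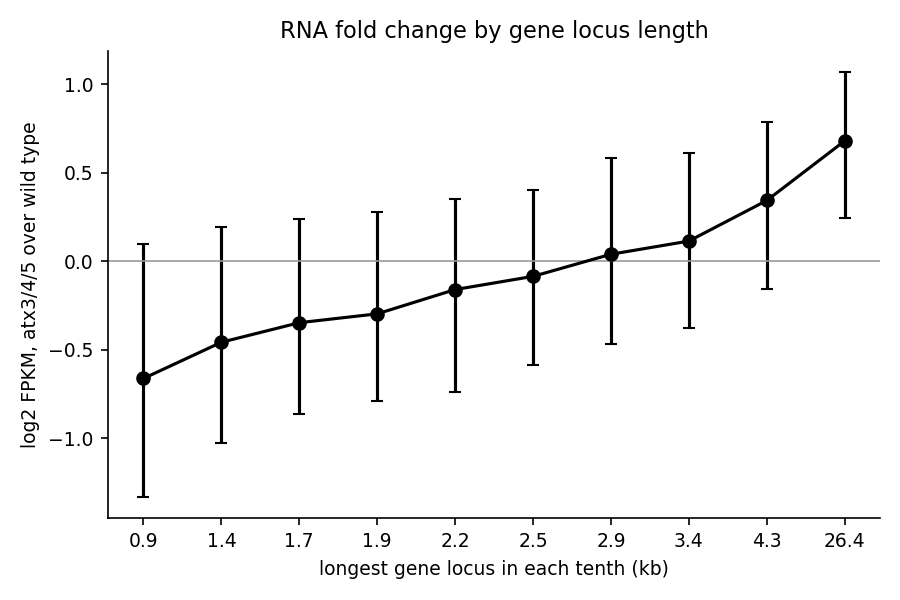
Median log2 ratio of FPKM, atx3/4/5 over wild type (y axis), in deciles of gene locus length, each marked by its longest locus in kb (x axis), from the authors' deposited table. Points are medians and bars run from the lower to the upper quartile; the median goes from -0.66 to 0.68.

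More H3K4me2 than H3K4me3 peaks were absent in atx3/4/5, but H3K4me2 peaks also have lower scores. Of 20585 wild-type H3K4me2 peaks 6491 had no counterpart in atx3/4/5, a share of 31.5% (95% interval 30.9 to 32.2). The mutant list was shorter, at 16650 peaks, and its peaks were narrower, with a median of 923 bp against 1122 bp. The bases under peaks came to 17.3 Mb in atx3/4/5 and 26.2 Mb in wild type, or 66.1%. Absent peaks were weaker, with a median score of 100.02 against 276 for those kept, but of the highest-scoring quintile 382 of 4117 (9.28%) were absent too. Among the 5 highest-scoring absent peaks were those over the carotenoid dioxygenase gene NCED5 (chromosome 1, 10571269 to 10572891), the plasmodesmata gene PDLP6 (chromosome 2, 291745 to 292721), the cytokinin synthesis gene IPT5 (chromosome 5, 6362061 to 6363494), the pair AT2G36090 and CASP1 (chromosome 2, 15158505 to 15159593) and AT4G16820 (chromosome 4, 9467618 to 9469158). Gained peaks numbered 1620, or 9.73% of the mutant list (9.28 to 10.2), with a median score of 67.7. Of the 5 highest-scoring gained peaks 4 lay on chromosome 3 between 14199493 and 14202458, at a ribosomal RNA repeat that includes AT3G41979, where reads may come from many copies. The other was on chromosome 2 at 3127 to 3648, near the end of the chromosome.

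Fewer H3K4me3 peaks were absent in atx3/4/5, in a list of stronger peaks. Of 14496 wild-type H3K4me3 peaks, 1427 were absent (9.84%, interval 9.36 to 10.3), and 497 of the 13622 mutant peaks were gained (3.65%, interval 3.34 to 3.98). The median score in wild type was 769 for H3K4me3 and 197 for H3K4me2. Weighted to the scores of the H3K4me2 peaks, H3K4me3 peaks were absent at 32.5%, so the overall shares do not rank the marks. Covered bases were 15.6 Mb, or 91.4% of wild type, and the median width was 1062 bp against 1080 bp. Nearly all losses were of weak peaks: 41.2% of the lowest-scoring quintile were absent, and 2 of 2899 in the highest. The 5 highest-scoring absent peaks lay over AT2G19780 (chromosome 2, 8522567 to 8524326), MSL5 (chromosome 3, 4972683 to 4974517), AT4G29140 (chromosome 4, 14368866 to 14370732), the pair AT1G50270 and AT1G50280, and AT4G12690. Of these genes only AT4G12690 was called in RNA, lower by a log2 fold change of -1.62 with a q of 0.0320 in the authors' deposited table. The 5 highest-scoring gained peaks lay over the receptor-like protein genes RLP28 (chromosome 2, 14031846 to 14033699) and RLP20 (chromosome 2, 10826652 to 10828868), the receptor-like kinase gene CRK36 (chromosome 4, 2232702 to 2234810), AT1G13470 and the pair AT4G00695 and AT4G00700. RLP20, CRK36, AT1G13470 and AT4G00700 were higher in RNA, with log2 fold changes of 4.35, 3.58, 3.34 and 4.76 in the authors' deposited table. RLP20 and AT4G00700 had a wild-type FPKM under 1. RLP28 had 6.24 with a q of 0.283 in the authors' deposited table, at an FPKM of only 0.0409 in wild type, and was not called, and AT4G00695 was not tested.

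In sdg2 the number of H3K4me3 peaks was not lower but the peaks were narrower and had lower scores. The list held 15569 peaks against 14496, with a median width of 675 bp against 1080 bp, so that they covered 11.2 Mb (65.5% of wild type). The median score was 401 in sdg2 and 769 in wild type. Of the wild-type peaks 1363 were absent (9.40%, interval 8.93 to 9.89), and 1730 of the mutant peaks were gained (11.1%, interval 10.6 to 11.6). Where a wild-type peak met exactly 1 sdg2 peak, as for 12441 peaks, the sdg2 peak was the narrower in 96.0%. Losses were spread over the scores more than in atx3/4/5, with 24.3% of the lowest quintile and 2.35% (68 of 2899) of the highest absent. With a rule that at least 50% of a wild-type peak be covered, the absent share became 25.1%. The highest score among absent peaks, 3100, was shared by 6 peaks, of which the first 5 in chromosome order are given. They lay over abundant photosynthesis genes and others: GAPA-2 (chromosome 1, 4392443 to 4394580), the Rubisco small subunit gene RBCS1A (chromosome 1, 25047788 to 25049549), the Calvin cycle gene CP12-2 with AT3G62400 and AT3G62422 (chromosome 3, 23090726 to 23093010), the non-coding GUT15 with SDH1-2 (chromosome 2, 7995426 to 7997418), and AT1G79245. Of the 5 highest-scoring gained peaks 3 lay at the ribosomal RNA repeat of chromosome 3. The others were over ABA3, which matures the cofactor of an abscisic acid synthesis enzyme, with its neighbour AT1G16550 (chromosome 1, 5665440 to 5666219), and over AT2G22600.

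**Figure D3:**
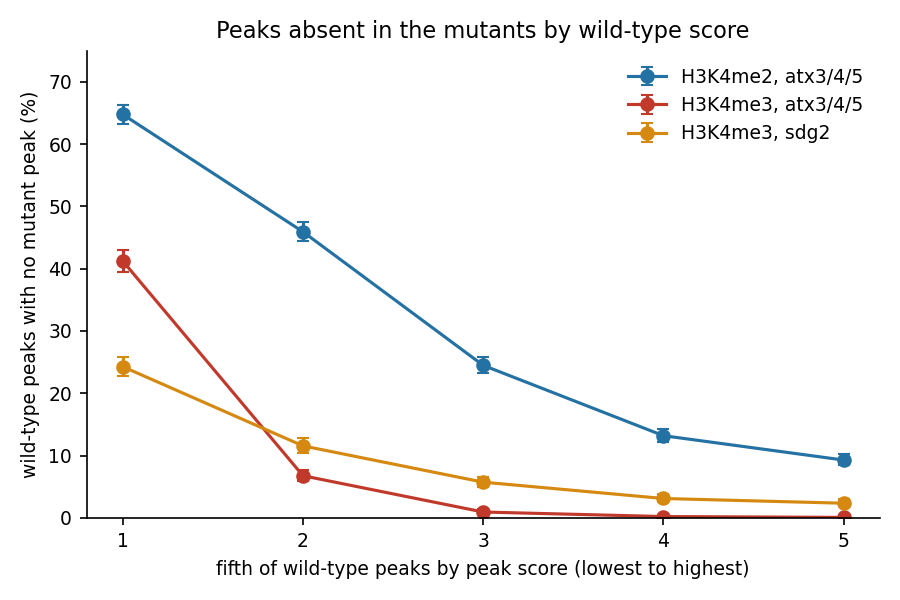
Share of wild-type peaks with no mutant peak (y axis, %) in quintiles of the wild-type peak score, from lowest to highest (x axis). Points are shares and bars exact 95% intervals, which cover counting only; H3K4me2 losses in atx3/4/5 reach 64.8% in the lowest quintile and 9.28% in the highest.

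**Figure D4:**
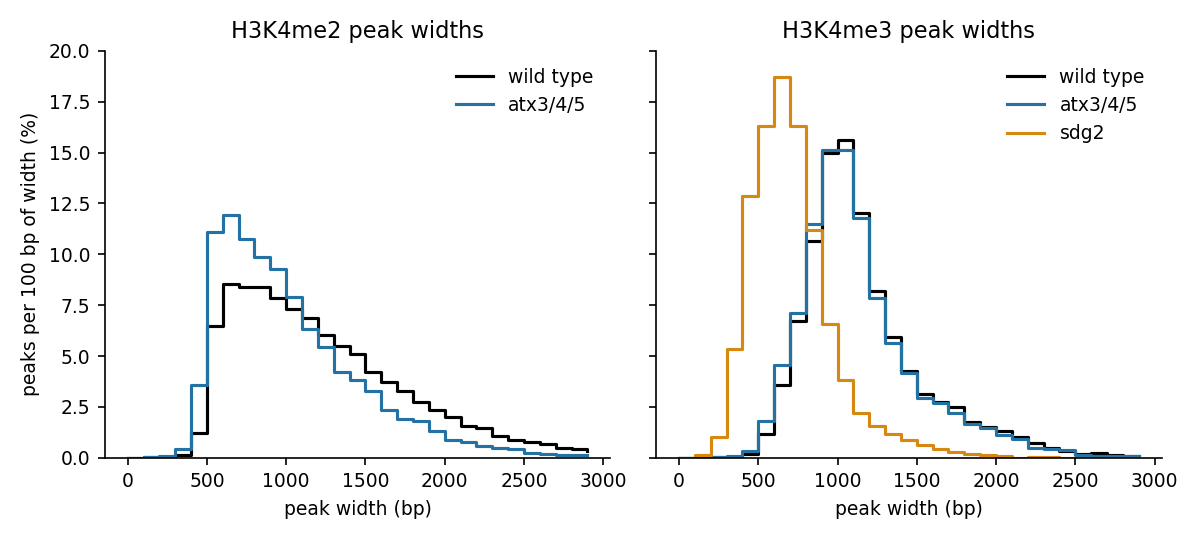
Distribution of peak widths in bp (x axis) as the share of peaks per 100 bp of width (y axis, %), for H3K4me2 on the left and H3K4me3 on the right. Each line is 1 library; the sdg2 H3K4me3 line lies left of the others, with a median of 675 bp against 1080 bp in wild type.

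Genes that lost H3K4me3 in both mutants were slightly more numerous than independent losses would give. Of 16692 genes with H3K4me3 in wild type, 1390 lost it in atx3/4/5, 1566 in sdg2, and 334 in both. Independent lists would share 130 genes, but weak peaks are lost more often in any list, and draws matched on the wild-type score shared 299 on average (276 to 322 in the central 95% of draws). The observed number was 1.12 times that average. The count depends on the rule: with at least 50% of the peak bases uncovered it was 611, against 522 in matched draws, or 1.17 times. Both comparisons use the same wild-type library, so part of the excess may come from it. Among list members that lost the mark in both were COR15A, BIP3, NAS4, MYB28, IAA1 and 3 small auxin genes (SAUR15, SAUR20 and SAUR24), and the cell wall genes EXPA5, XTH4, XTH7 and XTH16.

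In wild type, genes with H3K4me3 were transcribed and genes with H3K4me2 alone mostly were not. Of 33278 nuclear genes, 14178 (42.6%) carried both marks, 2514 (7.55%) H3K4me3 alone, 4002 H3K4me2 alone and 12584 (37.8%) neither. The median wild-type FPKM of these classes in the authors' deposited table was 8.99, 24.1, 0.219 and 0. Photosynthesis genes all carried H3K4me3 (32 of 32), and 15 of them H3K4me2. A median of 39.7% of the locus was under H3K4me3 peaks and 61.8% under H3K4me2 peaks, counted over marked genes with a locus of their own. In atx3/4/5 the share with both marks was 36.4% and that with H3K4me3 alone 11.1%, and the H3K4me2 peaks covered a median of 47.2% of the locus. In sdg2, H3K4me3 covered 27.0% of it.

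Genes that lost a peak in atx3/4/5 had lower ratios of mutant to wild-type RNA than genes of similar FPKM that carry the mark. The 2715 tested genes that lost H3K4me2 had a median log2 fold change of -0.34 in the authors' deposited table, below all random lists, whose medians ran from 0.03 to 0.12. Of these, 266 were called lower (9.80%) and 78 higher (2.87%) in the authors' deposited table, against 4.25% and 4.90% in random lists. For the 1088 genes that lost H3K4me3 the median was -0.81 in the authors' deposited table, again below all random lists (0.15 to 0.28), with 220 called lower (20.2%) and 12 higher. Genes that lost both marks numbered 386 among those tested, with 101 called lower and 1 higher in the authors' deposited table. Over genes with a locus of their own, the medians also lay below all random lists matched on FPKM and gene length. They were -0.33 for H3K4me2, against random medians of -0.12 to -0.02, and -0.79 for H3K4me3, against 0.01 to 0.16. The distance for H3K4me2 was smaller with this matching.

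The 10 largest falls among genes that lost a mark belonged to genes listed at 0 in atx3/4/5 in the authors' deposited table, so no fold is given. The most abundant in wild type were AT5G46720 (8.22), AT2G35345 (3.48), AT1G35513, a pseudogene, and AT1G44414 (2.79), by FPKM in the authors' deposited table. The group went on with AT1G69140, AT5G25990, AT3G46370, AT4G08991, AT2G18938 and DTA2, at 1.22 to 1.97 in wild type in the authors' deposited table. The 5 largest rises were of genes listed at 0 in wild type, AT5G44570 (3.36), AT4G25330 (1.78), AT2G32130, AT5G22560 and AT4G10940, by FPKM in atx3/4/5 in the authors' deposited table. Of the called genes named earlier, AT3G15780, AT2G41312, AT4G12690, PDLP6, COR15A and EXPA5 had lost both marks, EXPA3, SUC2 and AT1G55675 H3K4me3, and COR47, IAA3 and MYB34 H3K4me2, and all of them were lower in RNA. NIT2 and AT5G09570 had lost H3K4me2 and BIP3 had lost H3K4me3, yet these were higher in RNA. Of them, NIT2 had also gained H3K4me3 and BIP3 had gained H3K4me2.

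**Figure D5:**
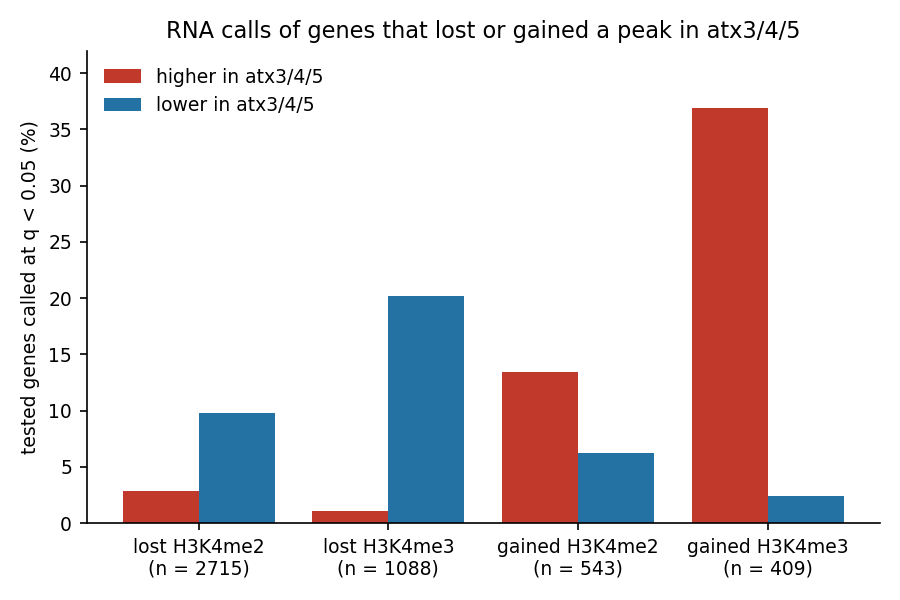
Share of tested genes called higher (red) or lower (blue) in atx3/4/5 in the authors' deposited table (y axis, %), for genes that lost or gained a peak in atx3/4/5 (x axis, number of tested genes below each pair). Of genes that lost H3K4me3, 20.2% were called lower and 12 of 1088 higher, and of genes that gained it 36.9% were called higher and 2.44% lower; there are no error bars, and the gained classes were added after the data had been seen.

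Set against draws of marked genes matched on wild-type peak score, some lists lost a mark more often than others. Of 52 comparisons of a list and a mark, 8 had a percentile above 97.5 and 2 below 2.5, with ties counted at their midpoint, and these draws were added after the data had been seen. Expansin and XTH genes lost H3K4me3 in atx3/4/5 at 8 of 13 marked members, EXPA3, EXPA5, EXPA11, XTH4, XTH7, XTH8, XTH9 and XTH16, against 3.12 in the average draw. They lost H3K4me2 at 9 of 17 members, against 4.22. Flowering time genes lost H3K4me2 at 7 of 11 members, FLC, MAF4, MAF5, TEM1, TEM2, FUL and LFY, against 3.00. Of these 7, FLC, MAF4 and LFY were not tested in RNA and the other 4 were not called. Their log2 fold changes in the authors' deposited table went both ways: MAF5 -5.49, TEM2 -0.41, FUL 0.99 and TEM1 1.04. MAF5 had a q of 0.464 there, at an FPKM of 2.30 in wild type. Neither the defence nor the clock genes lost H3K4me2 at any of their 19 marked members each, against 4.14 and 3.13. In sdg2 H3K4me3 was lost more often in 4 lists: photosynthesis genes with 10 of 32 members against 1.36, clock genes with 6 of 18 (CCA1, PRR7, PRR9, GI, LNK1 and LNK2) against 1.13, senescence genes with 5 of 9 against 1.47, and expansin and XTH genes with 5 of 13 against 2.13, a number level with the upper bound of its draws. The 10 photosynthesis genes include members of the RBCS, LHCB1 and LHCB2 families, whose near-identical copies may share reads, so they may not be separate losses. The draws were not matched on FPKM. Whether the lists differ between the mutants was not tested.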

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

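The tests of scaling, abundant genes and RNA integrity, the test of peak-calling fragment size, and both tests restricted to part of the peaks were chosen after the result was seen; the others here were set down before it.

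The number of H3K4me3 peaks moved in opposite directions in the mutants. It was 1073 above wild type in sdg2 and -874 relative to it in atx3/4/5, which singled it out as a difference between groups. With 1 library each this difference was not tested. LHCB1.3 (AT1G29930) stood out in data left out of the comparison: the authors' deposited table gives it an FPKM of 14877 in atx3/4/5 and lists it at 0 in wild type, with a status that marks it as not tested for too many reads. Whether the 0 reflects that status and not expression is unknown. Its near-identical neighbour LHCB1.1 has values in both genotypes, and H3K4me3 peaks overlap LHCB1.3 in all 3 genotypes.

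The first pattern weighed is the rise of RNA fold changes with gene length. The longest and shortest deciles differed by 1.34 in log2 (SE 0.0481), which a scaling factor shared by all genes cannot produce. Without genes at an FPKM of 100 or more the difference was 1.25, so abundant short genes do not carry it alone. Among genes with both marks in both genotypes it was 1.25 too, which argues against full loss of these peaks as the source. A mark counted as kept with 1 bp of overlap, so a partial loss of the marks was not tested. A difference in RNA integrity or size selection between the genotypes is a candidate explanation that stays open: the trend held in every quintile of mean FPKM, at least 0.70 in log2, but such a bias and an effect of the genotype itself cannot be told apart in values pooled per genotype. Lists of short or long genes should be read with this in mind.

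The second pattern is the absence of H3K4me2 peaks in atx3/4/5. A weaker H3K4me2 library would lose weak peaks first, and 9.28% (8.41 to 10.2) of the highest-scoring quintile were absent, which decides nothing for the list as a whole. For peaks without H3K4me3 it argues against that explanation, since 27.5% (24.3 to 30.9) of their highest-scoring 720 were absent. H3K4me3 peaks weighted to the H3K4me2 scores were absent at 32.5%, close to the 31.5% seen. A chromatin preparation poorer for both marks is therefore not excluded as a source of the average loss. Median scores of the marks did not move alike, however. For H3K4me3 the median was 800 in atx3/4/5 and 769 in wild type, and for H3K4me2 it was 128 and 197. These medians are over different sets of peaks. The H3K4me3 list of atx3/4/5 was the shorter, at 13622 peaks against 14496, and the absent peaks were weak, with a median score of 142. A shorter list can by itself have a higher median, so the value of 800 does not show an unchanged H3K4me3 signal. At strong peaks the values argue against a poorer preparation as the only source. Of the 9580 H3K4me3 peaks with a score of at least 510 only 0.668% were absent, against 9.28% of H3K4me2 peaks. Within that range the H3K4me3 peaks were not weighted to the H3K4me2 scores, and each mark has 1 library per genotype. Loss of methylation in the mutant stays open there as an untested hypothesis. Both comparisons of absent shares assume that scores of the 2 antibodies can be set side by side.

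The third pattern is the narrower H3K4me3 peaks of sdg2. A shorter fragment or shift size was predicted to take the same length from every peak, an assumption that was not checked. With peaks grouped by their width in atx3/4/5, which does not enter the difference, the widest quintile narrowed from wild type to sdg2 by 354.5 bp (SE 12.7) more than the narrowest, 602.5 bp against 248 bp. A weaker library was predicted to give peaks as wide as wild-type peaks of the same score, which was not checked either. In the 5 score quintiles the median sdg2 width was at most 72.7% of that in wild type (65.3% in the lowest case). In atx3/4/5 it was at most 98.2% and, in the case farthest from wild type, 1455 bp against 1532 bp. The first test argues against a shorter fragment or shift size only if its assumption holds. The second argues against a weaker library under the same condition. A reduced spread of H3K4me3 along genes in sdg2 is a hypothesis that stays open, with 1 library. A difference in shearing was not tested and sequencing depth is unknown, so these stay open as well.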

How the results depend on the processing

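All results below rest on values pooled by the authors or on 1 ChIP library, so read depth, the limit on weak peaks and low genes, is unknown. No paired analysis was possible because the RNA values are pooled per genotype and the columns carry no replicate number, and leaving out a replicate could not be run for the same reason. Length-aware settings and those with genes of their own locus were chosen after seeing the data. At a q under 0.01, which is stricter by construction, 440 genes were higher and 432 lower. The other RNA settings kept both counts within 1.5 times, and between 6 and 7 lists stood apart, the added list being senescence (0.33) with the FPKM filter and flavonoids (-0.70) with length matching. In the simulations 7% of lists with no shift stood apart, so a list close to the bounds can do so without an effect. The senescence, flavonoid and reference gene lists were that close. Peak shares moved with the overlap rule and the score filter. For H3K4me2 in atx3/4/5 the absent share was 38.0% when at least 50% of the peak had to be covered, 28.8% with a 200 bp gap, 21.1% for wild-type peaks with a score of at least 100, 40.2% with that score in both lists and 23.58% with equal numbers of peaks. For H3K4me3 in atx3/4/5 it was 7.12% for wild-type peaks with a score of at least 100 and 6.55% with equal numbers of peaks. For H3K4me3 in sdg2 it was 25.1% with at least 50% covered, 8.20% for wild-type peaks with a score of at least 100, 14.0% with that score in both lists and 12.1% with equal numbers of peaks. Counting a gene as lost when at least 50% of its peak bases were uncovered gave 611 genes that lost H3K4me3 in both mutants, where matched draws gave 522. The share of genes with both marks in wild type was 48.9% with loci extended by 500 bp, 35.7% with a score of at least 100 and 37.1% over genes with a locus of their own. Stricter scores remove peaks by construction; for the other shifts the cause was not tested. Medians of genes that lost a mark kept their sign and stayed below all random lists in every setting. Keeping organelle peaks moved nothing, as the lists hold none.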

Other observations

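The test of H3K4me2 loss at peaks without H3K4me3 was set down before its result was seen; the other tests and values here were chosen after the data had been seen.

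Genes that gained a mark in atx3/4/5 were called higher in RNA more often than other genes without that mark in wild type. Of 409 tested genes that gained H3K4me3, 151 were called higher and 10 lower in the authors' deposited table (36.9% and 2.44%), against 6.97% higher among other tested genes without the mark in wild type. Their median log2 fold change of 1.46 in the authors' deposited table lay above all random lists matched on FPKM, and that of genes with a locus of their own, 1.55, above all lists matched on FPKM and length. Of the defence list 8 genes, PR1, PR2, PAD3, NIMIN1, SARD1, PBS3, CBP60G and WRKY38, gained H3K4me3 in atx3/4/5, and no member lost it there. Whether 8 is more than chance would give was not tested. For the 543 genes that gained H3K4me2, 73 (13.4%) were called higher, against 4.02% of other genes without the mark, and 34 lower in the authors' deposited table. Their median, at -0.19 in the authors' deposited table, was below 0 but above all random lists.

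The FPKM sums of mitochondrial and plastid genes differed between the genotypes in opposite directions. FPKM values of the 146 mitochondrial genes summed to 2276 in atx3/4/5 and 413 in wild type in the authors' deposited table, and 4 of the 29 tested were called higher and none lower. The median log2 fold change of these 29 was only 0.40 in the authors' deposited table, so the sum rests on a part of the genes. The sum over the 133 plastid genes was 5057 against 10122, with 14 of 83 tested genes called lower and none higher in the authors' deposited table. The sum of FPKM over all genes was also lower in atx3/4/5, 717345 against 1099113 in the authors' deposited table.

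The share of genes that lost H3K4me3 ran differently along wild-type FPKM in the mutants. Deciles of wild-type FPKM in the authors' deposited table were taken over marked genes with a locus of their own. The share of these genes that lost the mark in atx3/4/5 fell from 28.5% in the lowest decile to 1.69% in the highest. In sdg2 it was 25.7% in the lowest, between 7.45% and 9.75% in the next 8, and 12.2% (10.5 to 14.1) in the highest. The median score of the wild-type peaks also climbed along the deciles, from 421 to 1329, so a dependence on transcription apart from peak strength was not tested.

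Most H3K4me3 peaks gained in sdg2 overlapped H3K4me2 peaks of wild type, but nearly as many of all sdg2 peaks did. Of 1730 such peaks 1387 (80.2%) overlapped a wild-type H3K4me2 peak, against 25.6% to 37.0% in 100 circular shifts along the chromosomes, and against 77.6% of all sdg2 peaks. Both marks lie mainly on genes, so the shifts were bound to fall below, and the values do not decide whether H3K4me3 arises at H3K4me2 regions in particular. A further hypothesis was that H3K4me2 is lost in atx3/4/5 more often where H3K4me3 is missing. In every quintile of the wild-type score the absent share was higher at peaks without H3K4me3, by 15.2 to 26.8 percentage points, and over all peaks it was 51.9% of 8063 without and 18.4% of 12522 with H3K4me3. That difference held at matched score and says nothing of its direction or of peak width, which was not matched.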
